A study of Mus musculus with 12 samples.

How the data were processed

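Cells of the stromal vascular fraction, the cells that remain when digested fat is freed of its mature adipocytes, were taken from the mesenteric fat of C57BL/6 mice. Per the labels' protocols, mice were perfused, the fat was separated from lymph nodes, intestine and omentum, digested with Liberase and DNase, filtered, and spun to remove the adipocyte layer. RNA was isolated with a column kit, and libraries were made with a stranded mRNA kit and sequenced on a HiSeq instrument. The labels name the cells as stromal vascular fraction, while the RNA protocol speaks of stromal cells of this fat, and no sort or gate is described. The sources used here do not spell out the 2 letters in front of each library title.

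The 12 libraries fall into 4 groups of 3, and the series' design text gives 3 mice per condition. Control mice were naive. Primary infection mice received 200 infective larvae of the intestinal roundworm Heligmosomoides polygyrus and were killed after 11 to 13 days. Recovery mice were infected, treated with 1 mg of the anthelmintic pyrantel pamoate, and left for 4 to 5 weeks. Secondary infection mice received a further 200 larvae at the end of recovery and were killed after 11 to 13 days. Pyrantel pamoate and the weeks of recovery are stated only for mice with a past infection, and their effects cannot be told apart from it. The labels state that mice were matched for age and sex.

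The authors deposited a table of raw counts per gene, with 47937 versioned Ensembl gene identifiers and 1 column per library. The counts are whole numbers and were not normalized. The submitters' processing notes name mm10 and DESeq2 without a role or version. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. In the table, 21753 genes had no count in any library. Symbols were found for 47224 identifiers, and the 713 without a symbol held 0.0512% to 0.0633% of a library's counts. Of the identifiers, 39106 equal those of GENCODE release M21, whose coordinates are on the same build (mm10), and coordinates are from that release.

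Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group labels, which left 13931, and libraries were scaled by TMM. One model with a mean per group was fitted to all 12 libraries, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.164. The 7 contrasts drawn from it were each of primary, recovery and secondary against control, secondary against primary, recovery against primary, secondary against recovery, and the difference between the response from recovery and the response from control. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene is said to have risen or fallen where the FDR was below 0.05, with no fold threshold. Errors of log2 fold changes are standard errors from the F statistic, and CPM values are means and SDs over 3 libraries, scaled by TMM, except that Adipoq, Xist and the Y-linked genes are given per total counts. All tests were two-sided.

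Before the data were examined, 19 lists of genes by function and 18 lists of cell type markers were written down from general knowledge, together with the samples, tests, alternatives and the rule for named genes. A list was tested with camera in limma 3.58.1, which compares its members with the other genes, using a preset correlation of 0.01 between genes, with adjustment over the lists of a contrast. Each test was repeated with a correlation estimated from the data. List counts are given over all genes tested and adjusted over the list alone. The number of members given for a list is of those the filter kept, and a gene could pass the filter through the libraries of a single group. The rule named, for primary, recovery and secondary against control and for secondary against primary, the 5 rising and 5 falling genes of largest fold with at least 5 CPM in the higher group, no predicted model symbol and no overlap of libraries. It added from each function list the 2 changed members of largest fold, at 1 CPM or more, where camera's adjusted p was below 0.05, otherwise 1, and 1 from each cell type list with such a p. The other contrasts took 4 rising and 4 falling genes, without the condition on overlap for the interaction. Further members are named where a list has few changed members, and the predicted gene Gm44876 is named as 1 of 3 calls; these were chosen after their values were seen.

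Where a group had no count of a gene, the fold is a lower bound against 3 counts over that group's libraries. Where it had 1 to 3 counts, the ratio of pooled CPM is given with an exact 95% counting interval. These intervals and bounds cover counting error only. Of 96 named genes, 10 overlap on the opposite strand another measured gene that has at least 10% of their counts. These are Ciita, Ddit3, Duoxa2, H2-DMa, Iglc1, Iglv1, Irf7, Plod2, Rasl10a and Uqcrb, while Trim65 overlaps one on the same strand. Il4ra, with 28240 counts, overlaps the antisense Gm44876, whose 1598 counts are below that share. Without the strand setting, reads of such pairs cannot be told apart, and their values are uncertain to that extent. Immunoglobulin variable genes, Iglc1, Serpina3g, Chil3 and the class II genes have close relatives with which the counting could share reads.

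Comparisons with the same controls were set beside 50 simulated data sets without effects, drawn from negative binomial counts with the fitted dispersions. Other splits of the libraries were counted for each contrast. Calls were tested on simulated counts of all libraries, with means pooled over all of them and 200 changed genes among 13931. The folds were applied to the primary libraries, and primary infection was compared with control. Changed genes were drawn only from those above a floor of mean expression, so the shares recovered do not hold for genes with few counts. The test recovered 14.4% of genes changed 1.5-fold, 66.7% of those changed 2-fold and 93.9% of those changed 4-fold, and 4.94% of calls were false. Alternatives were DESeq2 1.42.0 with its own filter, other scalings, filters, a fold threshold, a robust fit, only the libraries compared, a replicate block and leaving out each library. An offset for GC content and transcript length, fitted with mgcv 1.9.3, and DESeq2 on the 13931 genes were added after seeing the data. Tables and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

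Library totals ran from 5754572 to 11187395 counts, so 3 counts stood for 0.268 to 0.521 CPM in a single library. No column of the table was left out. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of 5.51 to 27.3 within groups.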

Results

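RNA of the stromal vascular fraction of mesenteric fat was sequenced from 12 C57BL/6 mice in 4 groups of 3: naive controls, mice with a primary infection by the intestinal roundworm Heligmosomoides polygyrus, mice that had recovered after drug treatment, and mice with a secondary infection. Total counts per library were 6748262 to 7816066 in controls, 7215169 to 11187395 in primary infection, 6321448 to 7311171 in recovery and 5754572 to 6918632 in secondary infection. The series title places the study in type 2 inflammation of the intestine and its lasting effect on this fat.

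The libraries carried a stromal profile. Pdgfra, a receptor of mesenchymal progenitors, stood at 849 ± 22.1 CPM in controls, 636 ± 42.7 CPM in primary infection, 825 ± 185 CPM in recovery and 708 ± 73.8 CPM in secondary infection (SD, n = 3 each). Ptprc, the common leukocyte antigen, was at 0.459 ± 0.358 CPM in controls, 1.21 ± 0.465 CPM in primary infection, 0.743 ± 0.309 CPM in recovery and 6.32 ± 0.529 CPM in secondary infection (SD, n = 3 each). The endothelial gene Pecam1 lay between 3.261 and 6.204 CPM as a group mean, the mesothelial gene Msln between 2.27 and 15.1 CPM, and the adipocyte gene Adipoq between 0.178 and 1.60 CPM. The actin-severing protein gelsolin, Gsn, alone took 8.21% to 11.6% of the counts of a library. Xist was read at 31.2 to 82.8 CPM in all 12 libraries, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in each, so the 12 libraries were alike by these genes of sex.

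On the principal components of log2 CPM the 3 secondary libraries lay apart from the other 9 along PC1, at 47.2 to 54.6, while controls lay at -30.5 to -24.9. Recovery library 3 stood apart from all others on PC2, at -47.7, and its values bear on each comparison with recovery and, through the shared fit, on the others. Recovery library 2 lay at -7.76 on PC1, nearer to the primary libraries (-1.94 to 8.47) than to recovery libraries 1 and 3 (-24.3 and -38.4). Libraries of a group correlated at a mean Pearson r of 0.979 in controls, 0.978 in primary, 0.968 in recovery and 0.977 in secondary infection, across genes.

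**Figure D1:**
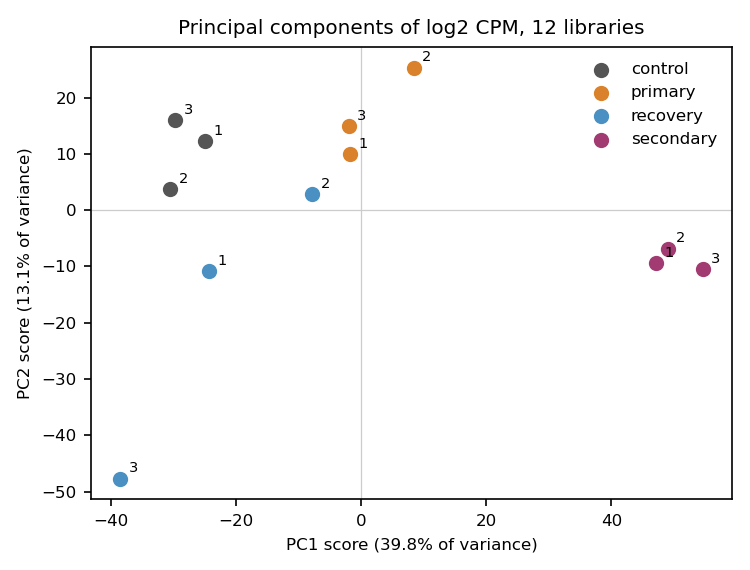
Scores of the 12 libraries on the first principal components of log2 CPM, PC1 (39.8% of the variance) on the horizontal axis and PC2 (13.1%) on the vertical axis, coloured by group and numbered by replicate. The secondary libraries lie at 47.2 to 54.6 on PC1, and recovery library 3 lies at -47.7 on PC2.

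**Figure D2:**
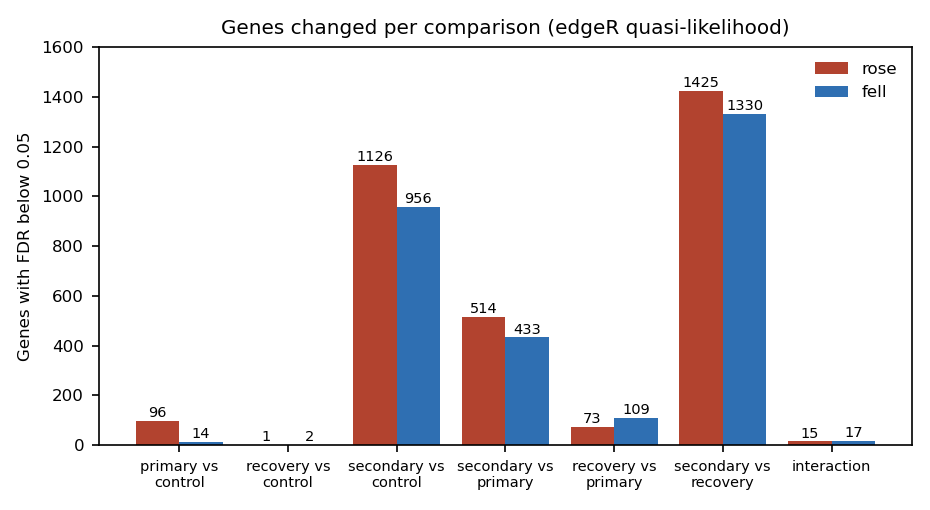
Number of genes with an FDR below 0.05 that rose or fell in each of the 7 comparisons, from the edgeR quasi-likelihood test over 13931 genes. Secondary infection against recovery gave 1425 rising and 1330 falling genes, and recovery against control gave 1 rising and 2 falling.

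Primary infection against control asked what a single infection of 11 to 13 days changes in this tissue. Mrgprg, an orphan receptor of the Mas-related family on chromosome 7 (143763710 to 143766993, mm10), rose from 3.32 ± 1.89 CPM to 466 ± 487 CPM (SD, n = 3 each), a log2 fold change of 7.11 ± 0.87 (SE, edgeR FDR 0.00165), with all 3 infected libraries at 97.1 CPM or more. Duox2, an oxidase that makes hydrogen peroxide, and its partner Duoxa2 rose from 2 and 1 counts over the 3 controls. Their pooled ratios were 142-fold (counting interval 38.9 to 1174) and 144-fold (25.5 to 5721), although the primary libraries ranged widely (11.4 ± 12.5 CPM and 5.68 ± 7.50 CPM, SD, n = 3). Saa3, an acute-phase serum amyloid, rose 45.1-fold by pooled counts (interval 15.2 to 221), and the serine protease inhibitor Serpina3g rose by 4.46 ± 0.56 on the log2 scale (SE, edgeR FDR 0.00170). Duox2, Duoxa2 and Saa3 kept their calls in 7, 3 and 5 of the 12 fits that left out 1 library. Over these fits the log2 fold change of Saa3 ran from 3.99 to 8.37. Il4ra, the receptor chain shared by IL-4 and IL-13, fell from 618 ± 137 CPM to 197 ± 47.6 CPM (SD, n = 3 each; log2 fold change -1.65 ± 0.30, edgeR FDR 0.0206). The other falling genes of largest fold were Rasgrf1, a Ras exchange factor, the neurotrophin Ntf3, the transcription factor Rfx2 and Trim65, with log2 fold changes of -1.16 to -0.91. In all, 110 of 13931 genes changed, 96 upward and 14 downward. Log2 fold changes fell with GC content (Spearman rho = -0.243 across 12189 genes), and with the offset for GC content and transcript length 144 genes changed.

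Of 16 collagens, 5 rose in primary infection (9 adjusted over the list alone) and the list's median log2 fold change was 0.54; Col8a1 rose by 1.75 ± 0.30, the fibril-associated Col14a1 by 0.81 ± 0.16, and Col1a2, Col3a1 and Col5a2 by 0.61 to 0.74. Of 25 matrix remodelling genes 4 rose (10 adjusted over the list alone), among them Postn, a matrix protein induced by IL-13, at 2.22 ± 0.43, and fibrillin, Fbn1, at 0.95 ± 0.20. Cthrc1, a gene of activated fibroblasts, was the 1 of 18 myofibroblast and TGF-beta genes that rose, at 2.17 ± 0.38. Both matrix lists stood above other genes by camera (adjusted p = 9.97e-09 and 2.84e-08), also with an estimated correlation (adjusted p = 0.0331 for each). With an estimated correlation and the replicate block, camera's adjusted p was 0.063 for the collagens and 0.0598 for matrix remodelling.

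Among inflammatory genes, 2 of 14 chemokines rose (7 adjusted over the list alone), Cxcl9 by 1.63 ± 0.30 and Ccl8 by 1.43 ± 0.30. Complement and acute phase genes gave 2 of 14 (7 adjusted over the list alone), Saa3 and C4b, the latter by 1.21 ± 0.13 (edgeR FDR 6.63e-04). Camera's adjusted p with an estimated correlation was 0.0178 for the chemokines and 0.0160 for complement. Of 20 genes of the IL-4 and IL-13 response, Retnla, a resistin-like product of alternatively activated macrophages, rose by 2.71 ± 0.48, Postn rose, and Il4ra fell (5 rose and 2 fell adjusted over the list alone; adjusted p = 0.0179, and 0.389 with an estimated correlation). Apoe rose by 0.88 ± 0.18, the 1 of 19 adipogenic and lipid genes that did (2 adjusted over the list alone). By edgeR 0 of 16 markers of Dpp4-positive progenitors passed over all genes (8 had an unadjusted p below 0.05; 7 rose adjusted over the list alone; median 0.41; adjusted p = 0.131 with an estimated correlation). Of 26 cell cycle genes, Cdk1 rose by 3.47 ± 0.75, from 0.273 CPM, and 25 had a positive fold (4 rose adjusted over the list alone; adjusted p = 0.417 with an estimated correlation). Immediate early and heat shock genes had a median of -0.25 with no call over all genes by edgeR (10 had an unadjusted p below 0.05; 8 of 25 fell adjusted over the list alone; adjusted p = 0.140 with an estimated correlation).

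Some leukocyte markers rose in the same libraries. Of 13 macrophage and monocyte markers 4 rose (10 rose and 1 fell adjusted over the list alone), Lyz2 by 1.98 ± 0.40 to 60.2 ± 34.3 CPM (SD, n = 3), with C1qb, C1qc and Ctss at 1.92 to 1.97. Laptm5 rose by 2.24 ± 0.43, 1 of 10 pan-leukocyte markers (6 adjusted over the list alone), and 2 of 7 MHC class II genes rose (7 adjusted over the list alone), H2-DMa by 1.41 ± 0.29 and H2-DMb1 by 1.35. With an estimated correlation camera gave an adjusted p of 0.0395 for the leukocyte list, 0.0395 for MHC class II and 0.0530 for macrophages. By edgeR 0 of 5 B and plasma cell genes passed over all genes (3 had an unadjusted p below 0.05; 3 rose adjusted over the list alone), with a median of 4.62, or 4.05 with a gene lacking control counts at its bound (adjusted p = 2.69e-05, and 0.0530 with an estimated correlation). Of 2 tested eosinophil and mast cell genes Ear2 rose, from 0.136 CPM in controls (2 adjusted over the list alone). The primary calls rested on few libraries: 10, 29 and 8 genes were called without control 1, 2 and 3, 19 and 9 without primary 1 and 2, and 171 to 179 without primary 3, recovery 2 or recovery 3. Of the 24 named genes Mrgprg, Serpina3g and C4b, 3 in all, stayed past the threshold in each of the 12 fits that left out 1 library.

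**Figure D3:**
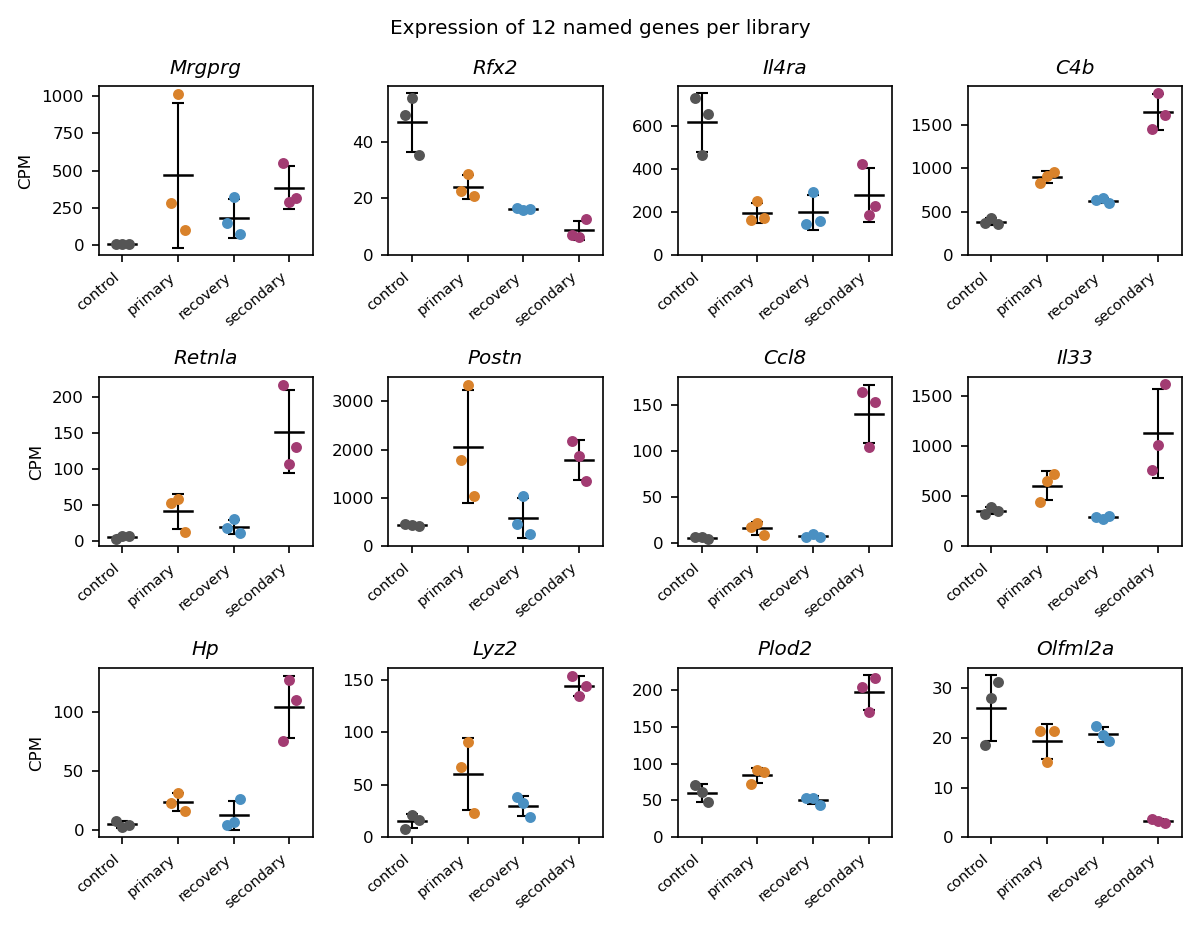
CPM of 12 named genes in the 12 libraries by group (points), with the mean (bar) and SD (error bar) of 3 libraries, on linear axes. Mrgprg lies at 3.32 CPM on average in controls and at 178 CPM or more in each other group, and Olfml2a lies at 3.34 CPM in secondary infection and at 19.3 CPM or more elsewhere.

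Recovery against control asked what still differs 4 to 5 weeks after the worms were cleared. Mrgprg was still high, at 178 ± 130 CPM against 3.32 ± 1.89 CPM (SD, n = 3 each), a log2 fold change of 5.72 ± 0.84 (SE, edgeR FDR 0.0264), and each recovery library was at 68.5 CPM or more. Rfx2, on chromosome 17 (56775897 to 56831013), fell from 46.7 ± 10.2 CPM to 16.3 ± 0.228 CPM (log2 fold change -1.52 ± 0.22, edgeR FDR 0.0264). Gm44876, a predicted antisense gene inside Il4ra (chromosome 7, 125570776 to 125572117), fell as well (log2 fold change -1.87 ± 0.29, edgeR FDR 0.0325), and its reads cannot be told apart from those of Il4ra without the strand setting. Il4ra itself was at 200 ± 81.2 CPM, with a log2 fold change of -1.63 ± 0.30 that missed the threshold (edgeR FDR 0.0629). These 3 genes were the sole calls among 13931 by edgeR; 1518 genes had an unadjusted p below 0.05 where 697 would by chance. DESeq2 called 116 over 26173 genes, without this filter, and 122 over the same 13931.

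By edgeR 0 of 414 list members passed over all genes in recovery (69 had an unadjusted p below 0.05), while DESeq2 called some, C4b, Il4ra and Herpud1 among them. Markers of leukocytes (median log2 fold change 0.69), macrophages (0.58), MHC class II cells (0.80) and B and plasma cells (4.76, or 4.05 with a gene lacking control counts at its bound) lay above other genes with the preset correlation, and unfolded protein response (-0.34), cholesterol synthesis (-0.46) and mesothelial genes (-1.33) below. With an estimated correlation the adjusted p of these 7 lists was 0.239 to 0.653. Adjusted over the list alone, 6 of 19 unfolded protein response genes fell and 3 of 5 B and plasma cell genes, 2 of 7 MHC class II genes and 1 of 10 leukocyte genes rose. Without control 1 or recovery 1 edgeR called no gene (1227 and 1346 had an unadjusted p below 0.05), and without control 2, control 3 or recovery 3 it called 1. It called 13 without recovery 2, 12 without secondary 1, 7, 9 and 8 without primary 1, 2 and 3, and 6 without secondary 3. Mrgprg and Rfx2 each kept their call in 8 of the 12 fits that left out 1 library, while their log2 fold changes stayed at 4.97 to 6.14 and -1.68 to -1.39. With a robust fit Mrgprg missed the threshold at an unchanged fold (edgeR FDR 0.170).

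All 3 recovery calls had changed in the same direction in primary infection. Without control 1 or control 3 no gene was shared, and without control 2 there was 1. Simulated data without effects, which hold few calls to share, gave 0 in each of 50 draws. Independent lists of these sizes would share 0.00689 rising and 0.00201 falling genes. Log2 fold changes of the 2 comparisons correlated at r = 0.449 across genes (Spearman rho = 0.282), below the simulated 0.504 that shared controls alone gave. Over the 10867 genes at 5 CPM or more their covariance was 0.0613 against a simulated 0.0241. Part of this excess may come from the shared controls, which with 3 libraries could not be divided.

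Secondary infection against control asked what a repeated infection changes relative to naive mice, and 2082 genes changed, 1126 upward and 956 downward. Immunoglobulin transcripts rose furthest: Ighg1, the IgG1 constant region, reached 268 ± 250 CPM (SD, n = 3) from 1 count in all controls, a pooled ratio of 5571 (counting interval 999 to 2.20e+05). Iglv1, Igkv3-10 and Iglc1 had 0 control counts and were at least 310-fold, 137-fold and 145-fold higher. The fitted log2 fold change of Igkv3-10 ran from 7.48 to 10.8 when 1 library was left out, so its size depended on single libraries. Chil3, a chitinase-like protein of alternatively activated macrophages, was at least 180-fold higher. Lsamp, an adhesion protein, Gpr165, Rasl10a, the olfactomedin-like gene Olfml2a and the stathmin Stmn4 fell furthest, with log2 fold changes of -3.07 to -2.84; Olfml2a went from 26.0 ± 6.59 CPM to 3.34 ± 0.349 CPM (SD, n = 3 each; edgeR FDR 1.75e-06).

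Of 20 IL-4 and IL-13 response genes 8 rose and Il4ra fell (10 and 1 adjusted over the list alone; adjusted p = 0.110 with an estimated correlation), led by Chil3 and by Il13ra2, the decoy receptor of IL-13, which was at least 39.4-fold higher. Of 15 alarmin and niche cytokine genes 5 rose and 1, Lif, fell (6 and 2 adjusted over the list alone; adjusted p = 0.0228, and 0.0798 with an estimated correlation). Among them the alarmin Il33 rose from 357 ± 35.6 CPM to 1128 ± 445 CPM (SD, n = 3 each; log2 fold change 1.66 ± 0.23, edgeR FDR 1.60e-04), and the stem cell factor Kitl rose by 1.63 ± 0.35. Chemokines gave 7 of 14 (8 rose and 1 fell adjusted over the list alone), with Ccl8 up by 4.54 ± 0.30 to 141 ± 31.5 CPM and Cxcl5 by 4.34 ± 0.85. When 1 library was left out, Ccl8 ran from 4.40 to 4.71 and Cxcl5 from 2.67 to 4.78. Complement and acute phase genes gave 9 of 14 (9 adjusted over the list alone), Hp, the hemoglobin-binding haptoglobin, by 4.34 ± 0.51, and Saa3 at a pooled 40.6-fold (interval 13.5 to 200). These last 2 lists kept their call with an estimated correlation (adjusted p = 0.00964 and 0.00727). In contrast, 5 of 25 interferon response genes fell (6 adjusted over the list alone), among them Isg15 (-1.07 ± 0.30) and Irf7 (-0.78 ± 0.18), with Irf1, Gbp2 and Bst2 at -0.70 to -0.47 (adjusted p = 0.466 with an estimated correlation).

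Of 16 collagens 8 rose in secondary infection, while Col6a3 fell, at -0.40 (11 and 1 adjusted over the list alone; adjusted p = 0.0781 with an estimated correlation); the fibrillar Col3a1 rose by 0.99 ± 0.15 from 7548 to 1.50e+04 CPM and Col8a1 by 0.96 ± 0.31. Matrix remodelling genes gave 10 of 25 (13 adjusted over the list alone; adjusted p = 0.0639 with an estimated correlation), Postn by 2.02 ± 0.42 and the collagen lysyl hydroxylase Plod2 by 1.71 ± 0.16. Cthrc1 rose by 1.94 ± 0.39, among 5 rising and 2 falling of 18 myofibroblast and TGF-beta genes (6 and 3 adjusted over the list alone). Of 19 adipogenic and lipid genes 6 rose and Pnpla2 fell (10 and 1 adjusted over the list alone; adjusted p = 0.0924 with an estimated correlation). Plin1, a lipid droplet protein, rose by 3.90 ± 0.86 and the fatty acid carrier Cd36 by 2.13 ± 0.36. Marker lists of stromal subsets moved in both directions: Bmp7, Sema3e, Dact2 and Efhd1 of the 16 Dpp4 markers fell and Fn1 rose, with Bmp7 at -2.30 ± 0.41 (4 fell and 2 rose adjusted over the list alone; adjusted p = 0.526 with an estimated correlation). Of 12 Icam1-positive preadipocyte markers 4 rose, Cd36 among them, and Dlk1, which restrains fat cell formation, fell (-2.69 ± 0.72), as did Gpc3 (5 rose and 2 fell adjusted over the list alone; adjusted p = 0.0781 with an estimated correlation). Of 12 F3-positive markers 5 fell, among them Igfbp3 (-1.57 ± 0.36), and Bgn rose (5 and 1 adjusted over the list alone; adjusted p = 0.516 with an estimated correlation).

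Leukocyte markers rose in nearly full sets of those tested. All 13 macrophage and monocyte markers rose (13 adjusted over the list alone; median 3.93), Ms4a7 by 4.50 ± 0.57, 9 of 10 pan-leukocyte markers (10 adjusted over the list alone), Cd53 by 4.45 ± 0.49, and all 7 MHC class II genes (7 adjusted over the list alone), the transactivator Ciita by 3.17 ± 0.77. Of 12 listed B and plasma cell genes 5 had enough counts to be tested, and 4 of these rose (5 adjusted over the list alone). Camera's adjusted p with an estimated correlation was 0.00964, 0.00964, 0.0181 and 0.0181 in this order. Beside Pdgfra at 708 CPM, Lyz2 was at 144 ± 9.79 CPM and Cd74 at 695 ± 216 CPM (SD, n = 3). Lyve1, shared by macrophages and lymphatic vessels, rose by 3.47 ± 0.62, 1 of 2 rising among the 3 tested of 7 lymphatic genes (2 adjusted over the list alone; adjusted p = 0.0924 with an estimated correlation). Msln rose by 1.40 ± 0.44, 1 of 10 mesothelial genes (0 adjusted over the list alone; adjusted p = 0.516 with an estimated correlation). Across 12189 genes the log2 fold change fell with GC content (Spearman rho = -0.328) and rose with transcript length (rho = 0.203). With an offset for both, added after seeing the data, 1961 genes changed, and Col8a1 and Isg15 missed the threshold (edgeR FDR 0.0791 and 0.121). The count was 1245 without control 3, 1305 without secondary 2 and 1200 without secondary 3. Of 42 named genes 36 kept their call in each of the 12 fits that left out 1 library; Col8a1 and Msln kept it in 6, Mki67 in 7, Isg15 in 8, Dlk1 in 9 and Plin1 in 11.

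**Figure D4:**
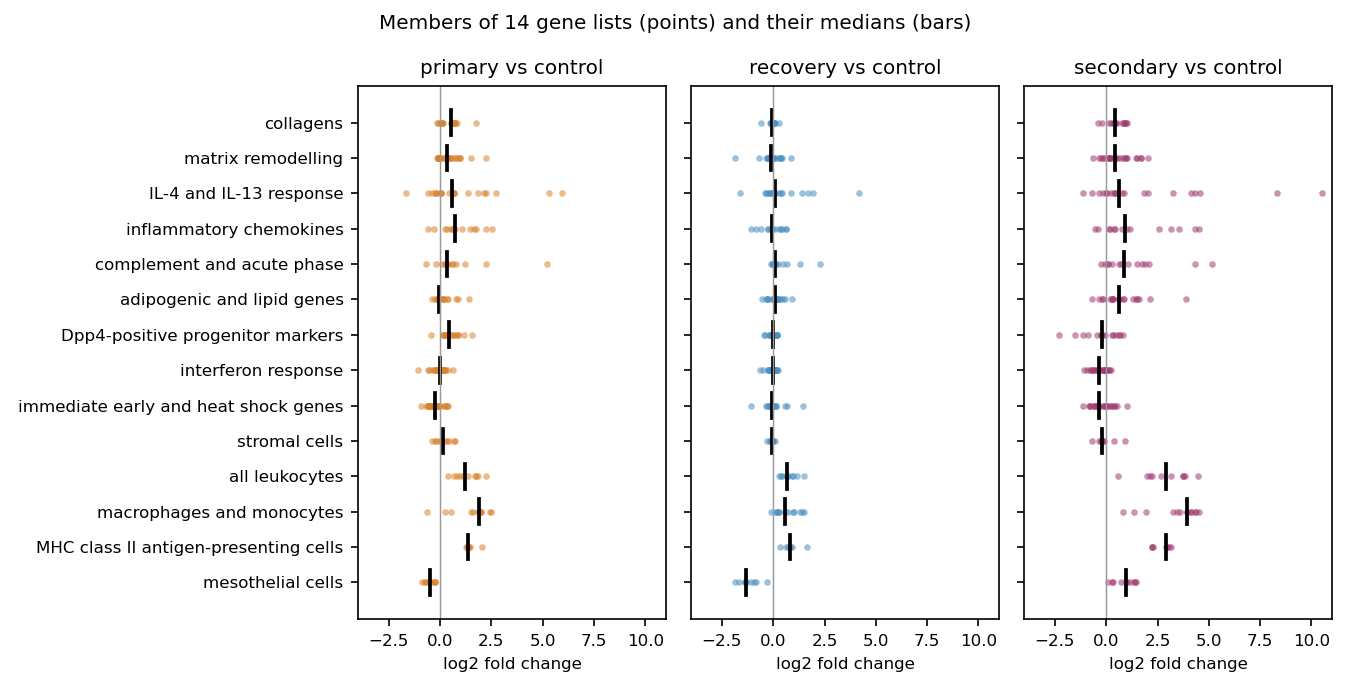
Log2 fold changes of the members (points) of 14 gene lists fixed before the data were examined and their medians (bars), for primary, recovery and secondary against control. The macrophage and monocyte median is 1.88, 0.58 and 3.93 in this order, and the collagen median is 0.54, -0.05 and 0.42. Chil3 and Il13ra2 had 0 counts in controls, so their plotted fitted values are no bounds.

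Secondary against primary infection compared the 2 infections at the same interval, and 947 genes changed, 514 upward and 433 downward. The immunoglobulin variable genes Igkv3-10, Ighv9-3, Igkv6-15, Igkv3-12 and Igkv17-121 had 0 counts in primary infection and were at least 68.7-fold to 172-fold higher. Igkv3-10, at the upper end, lost its call without primary 1 or primary 2. Its fitted log2 fold change ran from 7.48 to 10.8 when 1 library was left out. Stmn4, Fam167a, Rasl10a, Bmp7 and Olfml2a fell furthest, with log2 fold changes of -3.23 to -2.53. Of 20 IL-4 and IL-13 response genes 5 rose (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.145 with an estimated correlation), Chil3 by 5.20 ± 0.88 and the mannose receptor Mrc1 by 2.49 ± 0.40. Ccl8 rose by 3.11 ± 0.27 and Ccl4 by 2.09 ± 0.59, 2 of 3 rising chemokines among 14, while Cxcl10 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0783 with an estimated correlation). Kitl rose by 1.57 ± 0.34 and Ccl19, a lymphocyte-attracting chemokine, by 1.46 ± 0.41, among 5 rising niche cytokines of 15, and Il34 fell (5 and 1 adjusted over the list alone; adjusted p = 0.124 with an estimated correlation). Complement and acute phase genes gave 5 of 14 (6 adjusted over the list alone; adjusted p = 0.0470 with an estimated correlation), Lrg1 by 2.60 ± 0.41 and Hp by 2.12 ± 0.43.

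By edgeR 0 of 16 collagens passed (6 had an unadjusted p below 0.05, 0 adjusted over the list alone; median 0.13; camera adjusted p = 0.734). Of 25 matrix remodelling genes Lox, a collagen cross-linking enzyme, rose by 1.30 ± 0.21 together with Plod2 (2 rose and 1 fell adjusted over the list alone). Of 25 interferon response genes 5 fell (6 adjusted over the list alone; adjusted p = 0.369 with an estimated correlation), among them B2m, the class I light chain (-1.05 ± 0.15), and Irf7 (-0.81 ± 0.18). The Dpp4 progenitor list fell in 5 of 16 members (9 adjusted over the list alone; median -0.60; adjusted p = 1.04e-08, and 0.0783 with an estimated correlation), among them Bmp7 (-2.53 ± 0.40) and the Wnt regulator Dact2 (-2.02 ± 0.27). Plin1 rose by 2.51 ± 0.71 and Cd36 by 1.82 ± 0.35, among 3 rising lipid genes of 19 (5 adjusted over the list alone; adjusted p = 0.0783 with an estimated correlation), and Sdc1 by 0.93 ± 0.20. Sdc1, a cell surface proteoglycan, was among 3 rising and 1 falling of 12 Icam1-positive preadipocyte markers (5 and 1 adjusted over the list alone; adjusted p = 0.0783 with an estimated correlation). The TGF-beta receptor Tgfbr1 rose by 0.90 ± 0.20, among 3 rising and 1 falling of 18 myofibroblast and TGF-beta genes (4 and 1 adjusted over the list alone), and Egr2 by 0.84 ± 0.15, among 3 rising and 2 falling of 25 immediate early and heat shock genes (5 and 3 adjusted over the list alone). Mgp, which restrains calcification (-1.15 ± 0.20), the stromal matrix gene Mfap5 (-0.64 ± 0.17) and the clock gene Per2 (-1.48 ± 0.36) fell. Mfap5 was among 2 falling and 0 rising of 10 stromal markers (5 fell adjusted over the list alone, median -0.36). Camera's adjusted p of that list was 0.0128, and 0.135 with an estimated correlation. Whether dilution by RNA of other cell types lowered genes in this comparison was not tested. Of 19 unfolded protein response genes 3 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.00807, and 0.369 with an estimated correlation), Creld2 (-1.03 ± 0.22) and Trib3 (-0.82 ± 0.22) among the former. Uqcrb (-0.62 ± 0.17) was the 1 of 26 oxidative phosphorylation genes that fell (0 adjusted over the list alone; camera adjusted p = 0.0231, and 0.563 with an estimated correlation). Trib3 and Uqcrb missed the threshold with the GC and length offset (edgeR FDR 0.0991 and 0.0529).

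Macrophage markers rose in 12 of 13 (12 adjusted over the list alone), Ms4a7 by 3.00 ± 0.46, pan-leukocyte markers in 6 of 10 (9 adjusted over the list alone), Cd53 by 2.62 ± 0.40, and B and plasma cell genes in 4 of the 5 tested (4 adjusted over the list alone), Ighg1 by 7.999 ± 0.786. With an estimated correlation the adjusted p was 0.0287, 0.0287 and 0.0470. MHC class II genes gave 4 of 7 (6 adjusted over the list alone; adjusted p = 0.0783 with an estimated correlation), Cd74, the invariant chain, by 1.76 ± 0.33. Esam rose by 1.53 ± 0.31, 1 of 2 rising among 12 blood endothelial genes (3 adjusted over the list alone; adjusted p = 0.00180, and 0.305 with an estimated correlation). Mmrn1 rose by 2.32 ± 0.61, 1 of 3 lymphatic genes (1 adjusted over the list alone; adjusted p = 0.0206, and 0.135 with an estimated correlation). The mesothelial Lrrn4 rose by 2.24 ± 0.51, among 5 of 10 mesothelial genes (8 adjusted over the list alone; adjusted p = 0.244 with an estimated correlation). The count ranged from 430 without primary 1 and 439 without secondary 3 to 1413 without recovery 3, with 448 without primary 2 and 573 without secondary 2. Of 40 named genes 24 kept their call in each fit that left out 1 library; of 12 fits, Ccl4 kept it in 2, Plin1 in 3 (at 1.15 to 3.27, with 5.74 ± 6.27 CPM in secondary infection, SD, n = 3), Ccl19 in 5, and Mmrn1, Trib3 and Uqcrb in 7.

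Recovery against primary infection set the cleared against the ongoing state, and 182 genes changed, 73 upward and 109 downward. Log2 fold changes rose with GC content (Spearman rho = 0.337 across 12189 genes). The cAMP phosphodiesterase Pde4c rose by 3.11 ± 0.49, the granzyme Gzmm by 1.83 ± 0.39 and the transcription factor Zbtb16 by 1.52 ± 0.19 (edgeR FDR 0.00425). Agt, the precursor of angiotensin (-2.84 ± 0.62), Cthrc1 (-2.80 ± 0.41), Fam167a (-2.59 ± 0.49) and the carbonic anhydrase Car3 (-2.54 ± 0.52) fell. The count depended on single libraries: 3 without recovery 1, 8 without primary 2, 78 without primary 1, 79 without recovery 3 and 1120 without recovery 2. Of the genes named here Zbtb16 alone kept its call in each fit that left out 1 library.

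Secondary infection against recovery, the state it started from, changed 2755 genes, 1425 upward and 1330 downward. Log2 fold changes fell with GC content (Spearman rho = -0.399 across 12189 genes), the largest such trend by size of the 7 comparisons, and rose with transcript length (rho = 0.188). With the offset for both, 2221 genes changed, 1292 upward and 929 downward, and 1772 of them were among the 2755. Ighg1 stood at a pooled 1750-fold of its recovery level (counting interval 598 to 8488), and Igkv3-10, Igkv6-15 and Igkv3-12, without counts in recovery, were at least 51.8-fold to 129-fold higher. For Igkv3-10, at the upper end, the fitted log2 fold change ran from 7.48 to 10.8 when 1 library was left out. Ces1d, a carboxylesterase (-2.75 ± 0.35), Olfml2a (-2.64 ± 0.24), the methyltransferase Inmt (-2.54 ± 0.34) and Cys1 (-2.10 ± 0.25) fell. All 8 named genes kept their calls in each fit that left out 1 library, while the count of genes ran from 1323 without secondary 3, with 1651 without secondary 2, 1675 without recovery 3 and 1771 without recovery 1, to 3777 without recovery 2.

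The responses to the 2 infections, each against its own starting state, share no library and correlated at r = 0.549 across 13931 genes (Spearman rho = 0.368), where simulated data without effects gave -0.000301; genes are not independent replicates. The r was 0.154 over 26184 genes without the filter, and 0.433 to 0.521 when 1 library was left out. Of the genes called in both, 73 rose and 9 fell in the same direction and 0 moved in opposite directions, against 9.82 and 1.34 for independent lists. Of the 110 primary calls, 96 were also called in the same direction in secondary infection against control, and between primary and secondary infection 34 of the 110 moved further in that direction and 4 moved back. With shared controls these 2 comparisons correlated at r = 0.727 against a simulated 0.499, with a covariance of 0.169 against 0.0242 over genes at 5 CPM or more, and independent lists would share 7.76 rising and 0.961 falling genes.

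The interaction asked whether the response to infection differs between naive and recovered mice, and 32 of 13931 genes passed, 15 with a more positive log2 change from recovery and 17 with a more negative one. Recovered mice had also been given pyrantel pamoate, so past infection and drug cannot be told apart in it. Ccl8 rose more in the secondary response (difference 2.74 ± 0.43, SE, edgeR FDR 0.0178), from 7.80 CPM in recovery to 141 CPM against 6.04 to 16.1 CPM in the primary response. Podxl, Il4ra and Rgcc also had positive differences, of 2.35 ± 0.46, 2.14 ± 0.42 and 2.04 ± 0.29. Il4ra was below controls in primary infection (log2 fold change -1.65), in recovery (-1.63) and in secondary infection (-1.14). Its positive difference is therefore no rise above controls, since it fell in the primary response and was already low in recovery. Mrgprg, already high in recovery, had the largest negative difference, -6.00 ± 1.03, followed by Olfml2a, Stmn4 and the tubulin-binding Tppp3 at -2.20 to -1.81. The count was 1 to 9 without each of controls 1 to 3, primary 1 or 2, recovery 1 or 3, or secondary 2 or 3, 21 without secondary 1, 103 without primary 3 and 193 without recovery 2. None of the 8 named genes kept its call in each of the 12 fits that left out 1 library. Scaling by library size alone left 9 genes, 3 positive and 6 negative.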

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

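The tests of leukocyte RNA, of GC content and transcript length, of scaling, of dilution, of single recovery libraries and of reads from Il4ra were chosen only after the results were seen, and the number of drawn exchanges was raised after a smaller draw was seen.

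The test of the difference between the secondary and the primary response passed 32 genes. Its log2 differences were 2.74 for Ccl8, 2.35 for Podxl, 2.14 for Il4ra, 2.04 for Rgcc, -6.00 for Mrgprg, -2.20 for Olfml2a, -2.12 for Stmn4 and -1.81 for Tppp3. Exchanging infection history within infected and within uninfected libraries gave as many genes in 8 of 100 drawn exchanges, the real one included, and up to 310 against the real 32, so chance is not excluded. The 7 larger exchanges kept the 3 primary and the 3 secondary libraries together, which points to a structure of the samples, since these groups differed by 947 genes. For the correlation of the 2 responses, 1 of 100 regroupings, the real one, gave an r as large (0.548 with the likelihood fit used for the regroupings). The highest other was 0.404, and the largest other by size was -0.421, since the sign of r in a mixed regrouping is arbitrary. Chance is unlikely there, at the smallest share that 100 regroupings can give.

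Each comparison of 2 groups has 10 splits, too few for a share under 0.05. As many genes came from 1 split in each, the real one: 110 in primary infection against control (highest other 1), 3 in recovery against control (highest other 0), 2082 in secondary infection against control (highest other 0), 947 in secondary against primary infection (highest other 0), 182 in recovery against primary infection (highest other 3) and 2755 in secondary infection against recovery (highest other 0).

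Leukocyte markers were higher in secondary infection than in controls: 95.7% of 23 tested macrophage and pan-leukocyte markers rose. The trend with GC content and length is excluded as the cause, since the macrophage median stayed at 3.93 with the offset, and so is scaling, which moved the median of all genes by at most 0.0148. RNA of leukocytes in the stromal preparation may account for the pattern, with Lyz2 at 144 CPM, C1qb at 78.1 CPM, Cd74 at 695 CPM and Ptprc at 6.32 CPM in secondary infection. Of these lists, Lyve1 is also a lymphatic marker and Mrc1 is also in the IL-4 and IL-13 list. No sort or gate is described, so more leukocytes in the tissue and more leukocytes carried into the preparation are both open, and neither was tested apart.

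In secondary infection 956 genes were lower than in controls, with a median log2 fold change of -0.71. With the GC and length offset 70.9% of them were still called lower, at a median of -0.60, so that trend is excluded as the whole cause. Dilution by RNA of other cell types would lower all stromal transcripts alike, and the stromal marker median was -0.22 (SE 0.17). In a test against that median less 3 SE, a log2 fold change of -0.74, 63 genes were lower, 6.59% of those that fell. Dilution of the size these markers show is not their whole cause, where they come from the cells that the markers measure. The bound rests on 10 stromal markers that themselves ranged from -0.68 to 0.92. For the others dilution cannot be told apart from other causes of a lower level, because they did not pass below that bound. Which cells the genes that fell came from was not tested, for the 63 as for the others.

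Mrgprg, Rfx2 and Gm44876 differed from controls in the same direction in primary infection and in recovery. For each gene 3 of 3 recovery libraries lay outside the control range, so the difference was not confined to a single recovery library. This is no independent test. The genes were chosen by their recovery FDR, and the rule that named Mrgprg and Rfx2 asked for no overlap of libraries. Shared controls stay open: 0 of 50 simulated data sets without effects gave as many genes, but such data hold few calls to share, and 3 controls cannot be divided. For Gm44876, reads of the overlapping Il4ra may be the source, as the fold changes of the 2 genes differed by at most 0.581 SE. A change that outlasts the infection stays a hypothesis for Mrgprg and Rfx2, since the 10 splits are too few, although no single library accounts for their recovery fold changes (4.97 to 6.14 and -1.68 to -1.39 with 1 library left out). Effects of the drug, and of the age and handling of recovered and naive mice, were not tested.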

How the results depend on the processing

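The offset for GC content and transcript length and DESeq2 on the filtered genes were chosen after seeing the data. None of the named results reversed its direction in the settings in which it was tested, but calls were lost. Of 132 results, 65 lost their call with a fold threshold of 1.5, 17 with a robust fit, 16 with the block and 12 with library size alone. DESeq2 lost 9 (7 on the filtered genes), the offset 4, and leaving out 1 library 1 to 46. A filter at 5 CPM kept 104 of the results and lost the call of 1 of them. The named results were not followed with only the groups compared. Counts moved with no filter, the fold threshold, DESeq2, only the groups compared, the offset, library size alone, a robust fit, the block and leaving out 1 library, by amounts that depend on the comparison. As planned, DESeq2 tested 26173 genes, so tool and filter changed at once; on the same 13931 genes it gave 286, 122, 2304, 1250, 541, 2955 and 386 genes in the order below, so those moves remain with the tool alone.

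For primary infection against control the count of 110 genes became 642 with no filter, 7 with the fold threshold, 278 with DESeq2 and 219 with only the groups compared. For recovery against control, 3 became 422 with no filter, 0 with the fold threshold in edgeR, 9 with a robust fit (without Mrgprg, FDR 0.170), 6 with the replicate block, 116 with DESeq2, 13 with only the groups compared and 15 with the offset. For secondary infection against control, 2082 became 499 with the fold threshold, 2745 with no filter, 2250 with DESeq2 and 2798 with only the groups compared. For secondary against primary infection, 947 became 1592 with no filter and 158 with the fold threshold. For recovery against primary infection, 182 became 1057 with no filter, 6 with the fold threshold, 547 with DESeq2, 61 with only the groups compared and 295 with the offset. For secondary infection against recovery, 2755 became 402 with the fold threshold, 1814 with only the groups compared and 2221 with the offset. For the interaction, 32 became 9 with library size alone, 662 with no filter, 0 with the fold threshold, 11 with the block, 384 with DESeq2 and 79 with the offset. The correlation of 0.549 became 0.154 with no filter and 0.203 with DESeq2 over 26173 genes, but 0.544 with DESeq2 on the filtered genes, so its fall came with the added genes. The 3 genes changed the same way in primary infection and recovery became 125 with no filter, 0 with the fold threshold and 25 with DESeq2 on either set of genes. Mrgprg left them with a robust fit, through recovery, and Rfx2 with library size alone and with the block, through primary infection (FDR 0.0597 and 0.0722).

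Leaving out 1 library at a time gave 8 (control 3) to 179 (recovery 2) genes in primary infection against control, 0 (control 1 or recovery 1) to 13 (recovery 2) in recovery against control, 1200 (secondary 3) to 2962 (recovery 3) in secondary infection against control, and 430 (primary 1) to 1413 (recovery 3) in secondary against primary infection. It gave 3 (recovery 1) to 1120 (recovery 2) in recovery against primary infection, 1323 (secondary 3) to 3777 (recovery 2) in secondary infection against recovery, and 1 (primary 1) to 193 (recovery 2) in the interaction. The correlation ran from 0.433 (primary 2) to 0.521 (secondary 1), and the genes shared by primary infection and recovery from 0 (control 1, control 3 or recovery 1) to 6 (recovery 2).

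Replicate numbers do not pair the libraries: after removal of group means, libraries of the same number correlated at a mean r of -0.0343. With a block by number the counts were 78, 6, 1765, 756, 135, 2375 and 11 in the order above. With the block and an estimated correlation, camera passed no list in primary infection against control (lowest adjusted p 0.0598). The same held in secondary against primary infection (lowest camera adjusted p 0.0851). With 5754572 to 11187395 counts per library, genes near 3 counts over a group are known only by bounds or counting intervals.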

Other observations

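The test of the size of the 2 responses, given last, was planned before its result was seen, while its number of draws was raised after a smaller draw and its count by direction was added after the result.

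In secondary infection against control other lists gave the following counts. Of 26 cell cycle genes 5 rose (6 adjusted over the list alone; adjusted p = 0.516 with an estimated correlation), Cdk1 by 3.31 ± 0.78 and Mki67 at a pooled 21.1-fold (counting interval 5.42 to 180). Of 25 immediate early and heat shock genes 5 fell and Fosl2 rose (5 and 2 adjusted over the list alone; adjusted p = 0.369 with an estimated correlation), with the chaperone Hsph1 at -1.13 ± 0.24 and the stress factor Atf3 at -0.86 ± 0.16. Of 19 unfolded protein response genes 4 fell (6 fell and 1 rose adjusted over the list alone; adjusted p = 0.516 with an estimated correlation), Herpud1 (-1.19 ± 0.19) and Ddit3 (-0.84 ± 0.16). Of 15 clock genes 3 fell and Per1 rose (3 and 2 adjusted over the list alone; camera adjusted p = 0.223), and Per2 stood at -1.61 ± 0.36. Dio2, which activates thyroid hormone, rose by 3.27 ± 0.62, 1 of 2 rising among 5 thermogenic genes (2 adjusted over the list alone; camera adjusted p = 0.0835). By edgeR 0 of 19 cholesterol synthesis genes and 0 of 26 oxidative phosphorylation genes passed (2 and 5 had an unadjusted p below 0.05), with medians of 0.03 and -0.22; camera adjusted p of the latter was 0.0286, and 0.516 with an estimated correlation.

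Of 10 stromal markers Col1a1 rose by 0.92 ± 0.15 and Pdgfrb fell (-0.68 ± 0.15; 1 and 1 adjusted over the list alone). Pericyte and smooth muscle markers went both ways, with Rgs5 and Kcnj8 up by 1.94 ± 0.46 and 2.09 ± 0.55 and Cspg4 and Des at -2.23 ± 0.34 and -1.50 ± 0.32, among 8 (3 and 3 adjusted over the list alone). Flt1 rose by 1.40 ± 0.40, 1 of 12 blood endothelial genes, Plin1 was 1 of 4 adipocyte genes that rose, and Ncam1 rose by 1.92 ± 0.32, 1 of 2 Schwann cell genes. Il1rl1, the IL-33 receptor, rose by 3.45 ± 0.99, 1 of the 2 tested among 10 listed group 2 lymphocyte genes. Ear2 and Alox15 rose, the 2 tested of 14 listed eosinophil and mast cell genes. Retnlg, the 1 tested of 10 listed neutrophil genes, reached 3.91 CPM from 0 counts in controls. The 1 erythroid and the 1 intestinal gene tested did not pass, and no T cell or exocrine pancreas marker had enough counts to be tested.

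A hypothesis was that the second infection changed expression more than the first did, each against its own starting point, and the SD of log2 fold changes over genes was 1.52 times as large in the secondary response. An exchange of infection history is one split with its mirror image, so its larger SD was set over its smaller, and 7 of 100 drawn exchanges, the real one included, gave as large a ratio (highest other 2.11). As drawn, the secondary SD was the larger in 2 of the 7 (highest other 1.69) and the primary SD in 5. With each mirror image counted apart, 7 of 200 labellings had as large a ratio in the direction of the hypothesis. The 2 shares lie on either side of 0.05, and the exchanges carry the difference between primary and secondary infection, so the test leaves the hypothesis open.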
